A study of Homo sapiens with 6 samples.

How the data were processed

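Gene expression was measured by RNA sequencing of poly(A)-selected RNA in 6 libraries of MCF7 cells: parental DMSO (1 library), parental enzalutamide (2), AROE DMSO (1) and AROE enzalutamide (2). Groups and replicate numbers came from the sample titles. The treatment protocol, which reads the same for every sample, describes MCF7 cells with an inducible AR, low without and high with doxycycline at 800 ng/ml added 1 day before the drug. The labels do not say which libraries received doxycycline, so the AROE libraries are described here by their label. Per the file headers, the parental columns carry the word TET and the AROE columns the word DOX, and the enzalutamide columns of replicates 1 and 2 end in the numbers 10 and 20. The labels give a single dose of 10 µM for 24 h, on day 2, and what the header numbers stand for is not stated.

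The authors deposited 1 table per library with whole-number read counts per Ensembl gene, not normalized. Per the submitters' processing notes, STAR, HTSeq, edgeR and the hg38 build were used. Their versions, the annotation release and the strand setting of the counting are not given in the sources used here. Each table ended with 5 summary lines that name no gene (no feature, ambiguous, not unique and the like), which held between 15.1% and 16.0% of the total and stayed out of library sizes and tests. Library totals over genes ranged from 82797992 to 96116658, so counting error was small for most named genes, and the 10 most abundant genes took between 7.55% and 8.53% of counts. The 2 enzalutamide libraries of each population were counted as separate replicates because the labels call them biological replicates. Their counts differed by more than sampling noise, with chi-square per degree of freedom of 33.5 in parental and 14.0 in AROE cells, as separate preparations of a single culture would too.

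Of 58395 gene identifiers, 57754 were matched to symbols in a table of gene names and 58275 to GENCODE release 29 on GRCh38 (hg38), which gave coordinates, GC shares and transcript lengths, and 120 were in neither. GENCODE was matched by identifier and is not stated to be the authors' annotation.

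Differential expression was tested with edgeR 4.0.16 in R 4.3.3, using TMM scaling (factors 0.984 to 1.03), filterByExpr by group, which kept 23400 genes and left out 34995, and the quasi-likelihood F test, two-sided. Adjusted p were computed with the Benjamini-Hochberg method over all genes tested, and genes with an adjusted p under 0.05 were counted as changed. A fit with 4 groups over all 6 libraries, with 2 residual degrees of freedom before moderation, gave enzalutamide against DMSO in each population, the difference of these effects, and AROE against parental cells under enzalutamide. An additive fit with the population as a term and 3 residual degrees of freedom gave the effect over both populations. With a single DMSO library per population, the 4-group fit takes its spread from the enzalutamide pairs (biological coefficient of variation 0.113). The additive fit (0.175) also takes it from the difference of the drug effects between the populations, in which both DMSO libraries enter. The standard error of a log2 fold change was its size over the square root of F. CPM used the TMM-scaled totals. The 2 DMSO libraries were compared as values, with 0.5 added to each count, a threshold of 1 log2 unit at a mean of at least 5 CPM, and exact 95% intervals that cover counting error only, since reads without molecular identifiers are not independent molecules.

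There were 17 gene lists with 303 entries, on androgen response, apocrine breast, estrogen response, luminal identity, steroid receptors, cell cycle, sterol and lipid synthesis, xenobiotic metabolism, integrated stress, unfolded protein, interferon response, hypoxia and glycolysis, p53 targets, mitochondrially encoded genes, immediate early genes, basal and mesenchymal genes, and replication-dependent histones. The lists, the tests and the naming rule were set before the data were examined. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, two-sided and adjusted over the 17 lists of a comparison, and again with an estimated correlation. Genes were named by rule: AR first; up to 8 per direction with the largest change among those that passed, with a mean of at least 5 CPM, a symbol that is no clone name, and each enzalutamide library on the same side of DMSO; up to 4 members per list with the smallest p, and the steroid receptors. Where fewer than 5 passed in a direction, the 5 with the smallest p were given, and for the DMSO pair the 8 largest ratios per direction.

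Alternatives were median-ratio size factors, library totals alone, no filter, at least 5 CPM in at least 2 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out, fits on the groups compared alone, and other thresholds. After the data were seen, a correction for GC content was added, a loess trend (span 0.3) of each library's log2 CPM on the GC share of the longest transcript over 11434 genes with a mean log2 CPM of at least 2, entered as offsets. The trend was also combined with transcript length and with the block. GC shares were known for 99.8% of the genes tested.

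The scripts were tested on simulated data with 200 changed genes, 50 per fold size. Without a simulated GC trend, in the parental comparison (22455 genes) 32% of 1.5-fold, 84% of 2-fold and 98% of 3-fold changes were recovered, with 3 false calls. False calls in this setting numbered 26 in the AROE comparison, 18 for the difference, 16 under enzalutamide and 10 over both populations. Of 50 changes at each of 1.5-, 2-, 3- and 4-fold, the AROE comparison recovered 19, 44, 47 and 50. The difference comparison recovered 6, 31, 46 and 46. In both of these comparisons, false calls took a larger share of all calls than the 0.05 threshold is meant to allow. With the GC trend of the real libraries simulated and left uncorrected, false calls numbered 3 in the parental, 2765 in the AROE (22375 genes) and 1841 in the difference comparison (22403 genes), against 11, 7 and 8 with the correction. The simulated trend was the one the correction had fitted, so this run could not test whether the correction captures all of the real trend. For the list test, simulated over both populations (23400 genes), a raised list of 20 genes had an adjusted p of 6.36e-22 by camera and 0 of 200 unchanged lists passed. The simulated genes varied independently of each other, so this run could not test the preset inter-gene correlation. Figures were drawn with matplotlib 3.10.9. Reads, and any measurement beyond these count tables, were not analysed here.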

Results

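Poly(A)-selected RNA was sequenced from MCF7 cells, an established human breast cancer line that expresses the estrogen receptor. Parental cells and a population labelled AROE, named for overexpression of the androgen receptor (AR), each received either the DMSO vehicle or enzalutamide, a drug that blocks the ligand-binding domain of AR. The labels give 10 µM enzalutamide for 24 h. There were 6 libraries in 4 groups, with 1 DMSO library and 2 enzalutamide libraries, labelled biological replicates, from each population. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure the spread between these libraries, which could in part be technical. Reads counted in genes numbered 94586350 in parental DMSO, 91728111 and 88913381 in the parental enzalutamide libraries, 96116658 in AROE DMSO, and 94238556 and 82797992 in the AROE enzalutamide libraries. Each library detected between 29365 and 30566 genes. Levels are CPM, counts scaled to the normalized library total, with mean ± SD over the 2 enzalutamide libraries and a single value for DMSO, which had no replicate. The lone DMSO libraries were assumed to vary as the enzalutamide pairs did.

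The libraries differed in how their counts followed the GC content of genes. Over the top decile of GC share among 11434 expressed genes, the median deviation from the gene mean was -0.63 log2 units in AROE DMSO and -0.28 in parental enzalutamide replicate 2. The same genes lay at 0.05 in parental DMSO, 0.13 in parental enzalutamide replicate 1, and 0.33 and 0.42 in the AROE enzalutamide libraries. A correction for this trend was added after it was seen, and corrected values are given for the counts of changed genes and for some of the genes and lists.

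**Figure D1:**
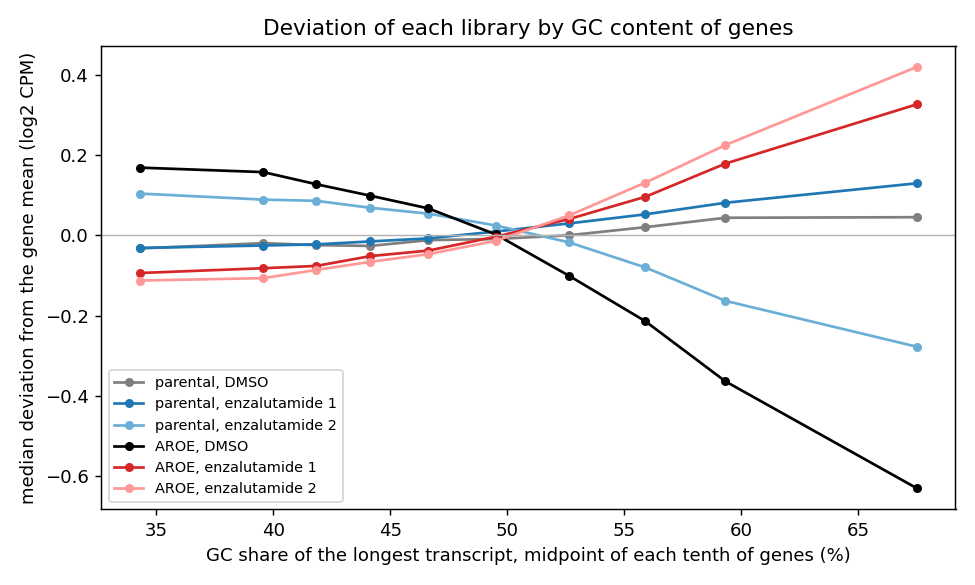
Median deviation of each of the 6 libraries from the gene mean (log2 CPM) against the GC share of the longest transcript (percent), with 1 point per decile of 11434 genes and 1 line per library. The AROE DMSO line ends lowest, at -0.63, and the AROE enzalutamide lines end highest, at 0.33 and 0.42.

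AR (ENSG00000169083, chromosome X, 67544032 to 67730619 in hg38), the nuclear receptor for androgens and the gene named in the AROE label, was higher in the AROE libraries. Its level was 67.5 CPM in parental DMSO and 124.1 CPM in AROE DMSO, from 6460 and 12246 reads. Under enzalutamide it was 51.9 ± 4.22 CPM in parental cells and 103.9 ± 10.2 CPM in AROE cells (SD, n = 2 each). The AROE to parental ratio was 2.00-fold under enzalutamide, a log2 difference of 1.00 (SE 0.10), with an adjusted p of 0.00938 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. AR did not pass with at least 5 CPM required in 2 libraries or in a fit of the 4 enzalutamide libraries alone, where its log2 difference was 1.01 in each. In the DMSO pair the ratio was 1.84-fold (95% counting interval of the log2 ratio 0.84 to 0.92, which covers counting error only). The direction fitted the labels in every library. Between enzalutamide and DMSO, AR differed by -0.38 log2 units in parental cells (SE 0.12) and -0.26 in AROE cells, with adjusted p of 0.306 and 0.183 in the same test.

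In parental cells, the question was what the AR antagonist changed at the cells' own AR level. The iron-oxidising plasma protein ceruloplasmin (CP) rose from 5.38 CPM in DMSO to 29.8 ± 5.94 CPM under enzalutamide (SD, n = 2), or 5.55-fold. STRA6, the membrane receptor for retinol-binding protein, rose 4.91-fold, from 3.60 to 17.7 ± 1.50 CPM, and DHRS3, which reduces retinaldehyde to retinol, rose 2.72-fold, from 50.1 to 136.2 ± 0.362 CPM. The lowered genes included CAV1, the main coat protein of caveolae, which fell from 111.7 to 42.0 ± 10.4 CPM, and MME, the membrane peptidase neprilysin, which fell from 22.3 to 9.18 ± 0.660 CPM. The adjusted p in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.000387 for DHRS3, 0.000542 for CP, 0.00489 for STRA6, 0.00534 for MME and 0.0200 for CAV1. CP lies on chromosome 3 (149162410 to 149222055), STRA6 on chromosome 15 (74179466 to 74212267), DHRS3 on chromosome 1 (12567910 to 12617731), CAV1 on chromosome 7 (116524785 to 116561184) and MME on chromosome 3 (155024124 to 155183729), all in hg38.

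Other genes with large increases in parental cells were the long noncoding RNA NRAD1 (log2 2.00), the ubiquitin ligase TRIM31 (1.97), KDR (1.80), which encodes a receptor for VEGF, the serine protease inhibitor SERPINA5 (1.56) and SPRY4 (1.37), an inhibitor of growth factor signalling. Among the lowered genes, ANKRD35 changed by -1.55, BNIPL by -1.39, the potassium channel subunit KCNJ8 by -1.32, the desmosomal plakophilin PKP1 by -1.31, the kallikrein KLK11 by -1.15 and the neuropeptide Y receptor NPY1R by -1.14. TRIM31, SPRY4, MME, STRA6, CP and NPY1R each overlap another annotated gene, and the strand of counting was not given in the sources used here, so their counts could hold reads of the neighbour. In total 119 genes changed of 23400 tested, 62 higher and 57 lower, and 2055 had an unadjusted p under 0.05.

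The fixed list of 13 measured replication-dependent histone genes, whose transcripts mostly end without a poly(A) tail, was lower under enzalutamide in parental cells. Since the RNA was poly(A)-selected, the list also served as a sign of RNA selection, and selection and expression cannot be told apart here. H2AC6 (log2 -0.79) and H2BC8 (-0.99) fell among all genes, 10 members fell with p adjusted over the list alone, and all 13 had a negative log2 change, with a median of -0.91. The camera test gave an adjusted p of 5.62e-09 with the preset correlation and an adjusted p of 0.961 with an estimated correlation. Members of the same histone family are similar in sequence, so reads could be shared between them or left out as not unique, and single values are uncertain. The histone list lay above its gene means in both DMSO libraries, by 0.61 log2 units in parental and 0.35 in AROE cells, and below them in all 4 enzalutamide libraries, at -0.08 and -0.36 in parental and -0.17 and -0.35 in AROE cells.

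The integrated stress list, targets and partners of the transcription factor ATF4, was higher in parental cells, with a median log2 change of 0.60 over 16 members. None passed over all genes in edgeR's quasi-likelihood test, while 10 were higher and 1, DDIT4, was lower adjusted over the list alone. The cystine transporter SLC7A11 was at 3.61 CPM in DMSO and 17.3 ± 12.1 CPM under enzalutamide (log2 2.26, SE 0.60), and PHGDH, the first enzyme of serine synthesis, at 27.7 and 71.4 ± 31.7 CPM. The camera adjusted p was 0.000784, against an adjusted p of 0.961 with an estimated correlation, and was 0.131 without parental enzalutamide replicate 2.

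All 6 steroid receptor genes had negative changes in parental cells, with a median of -0.45, and 4 were lower adjusted over the list alone, though 0 passed over all genes. Of the 6, ESR2 (log2 -0.51, SE 0.34) and NR3C2 (-1.51, SE 0.84) were at low levels, with means of 0.97 and 0.16 CPM over all libraries. ESR1, the estrogen receptor, was at 341.0 CPM in DMSO and 264.9 ± 24.1 CPM under enzalutamide, and NR3C1, the glucocorticoid receptor, at 68.1 and 54.3 ± 1.84 CPM. The camera adjusted p was 0.00262 (adjusted p 0.961 with an estimated correlation). AR, ESR1 and NR3C1 fell with the GC correction, with log2 changes of -0.41, -0.40 and -0.38.

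Of 24 measured androgen response genes, 3 rose and 0 fell in parental cells, and 6 rose adjusted over the list alone. TMPRSS2, a serine protease that androgens induce in prostate cells, rose from 54.1 to 96.5 ± 5.09 CPM. ALDH1A3, which makes retinoic acid, rose from 29.4 to 61.4 ± 9.42 CPM, and the exporter ABCC4 from 17.3 to 29.9 ± 2.48 CPM. With the GC correction 4 rose and 0 fell over all genes, and 8 rose and 4 fell adjusted over the list alone. The list's camera adjusted p of 0.0302 went with an adjusted p of 0.961 under an estimated correlation, 0.0992 with the GC correction, and 0.0723, 0.135, 0.0501 and 0.0508 without parental replicate 1, parental replicate 2, AROE replicate 1 and AROE replicate 2 under enzalutamide. The cell cycle list of 27 genes was also higher by camera (adjusted p 0.0120; adjusted p 0.961 with an estimated correlation). Its 7 genes that were higher adjusted over the list alone included the replication factors MCM6 (log2 0.46), CDC6 (0.45), MCM3 (0.37) and PCNA (0.36), while 0 passed over all genes. Of the 27 genes, 18 had positive changes, and PLK1 (-0.39) and AURKA (-0.19) were among those that did not. The cell cycle adjusted p was 0.259 without parental replicate 1 and 0.0501 and 0.0508 without AROE replicates 1 and 2 under enzalutamide.

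Single members of other lists also changed in parental cells. HK2, a hexokinase of the hypoxia and glycolysis list, rose from 73.1 to 120.7 ± 11.1 CPM, and GDF15, a secreted stress cytokine of the p53 list, from 14.1 to 34.3 ± 0.226 CPM. The 12 lists without a call had camera adjusted p between 0.186, for mitochondrially encoded genes, and 0.900. They covered apocrine breast, estrogen response, luminal identity, sterol and lipid synthesis, xenobiotic metabolism, unfolded protein response, interferon response, hypoxia and glycolysis, p53 targets, mitochondrially encoded, immediate early, and basal or mesenchymal genes, the last serving as markers of other cells.

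The parental count was 586 with the GC correction, 261 with DESeq2, 544 with no filter on low counts, and 4 (CP, TGFBI, DHRS3 and KRT4, of which TGFBI and KRT4 are named here after their values were seen) with at least 5 CPM required in 2 libraries. It was 2340 without parental replicate 1, 304 without parental replicate 2, and 350 without either of the AROE replicates under enzalutamide.

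In AROE cells, the same treatment was examined at the higher AR level. STRA6 rose from 2.56 CPM in DMSO to 21.0 ± 7.69 CPM under enzalutamide (SD, n = 2; 8.19-fold), CP rose from 4.60 to 24.4 ± 3.75 CPM (5.30-fold), and DHRS3 rose from 35.3 to 166.7 ± 8.94 CPM. GDF15 rose 6.50-fold, from 7.45 to 48.4 ± 15.2 CPM, and the sphingomyelinase SMPD3 rose from 2.02 to 12.5 ± 1.83 CPM. MME fell from 25.2 to 7.66 ± 1.09 CPM, NPY1R from 33.2 to 11.7 ± 1.75 CPM and CAV1 from 118.8 to 41.5 ± 13.6 CPM. BNIPL (log2 -1.72), KCNJ8 (-1.58), the death ligand TNFSF10 (-1.40), the phospholipid flippase ATP8A1 (-1.40) and KYNU (-1.39), an enzyme of tryptophan breakdown, also fell. Adjusted p in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment lay between 0.000178, for genes including CP, GDF15, SMPD3 and ISG15, and 0.00110, for KCNJ8, over the genes with the largest changes.

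The cytokine MIF (log2 3.43), the tight junction protein CLDN3 (2.54), the ubiquitin-like interferon-induced protein ISG15 (2.43) and the synaptic adhesion protein LRFN4 (2.42) also rose in AROE cells. The GC correction gave them 2.18, 1.06, 1.46 and 1.02, and it gave STRA6 2.26, GDF15 1.77 and CP 2.66; all 7 passed the test in both fits. MIF and LRFN4 overlap other annotated genes. In total 3007 genes rose and 1168 fell, a share of 72.0% higher. The share was 59.2% higher when libraries were scaled by their totals alone (2728 and 1884 genes) and 51.3% higher with the GC correction (1190 and 1131 genes).

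The interferon response list was higher in AROE cells, where 8 of 21 measured members rose and 0 fell, over all genes and adjusted over the list alone alike. ISG15 rose from 17.0 to 91.8 ± 10.5 CPM, the antiviral oligoadenylate synthetase OAS3 from 79.9 to 175.6 ± 17.6 CPM, IFI27 from 60.5 to 164.3 ± 22.8 CPM, and BST2, which tethers budding virions, from 3.17 to 10.6 ± 0.718 CPM. The median log2 change was 0.39 and the camera adjusted p 0.00206, against an adjusted p of 0.747 with an estimated correlation. With the GC correction 10 members rose and the median was 0.53.

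The integrated stress list rose in 10 of 16 members in AROE cells, with 13 adjusted over the list alone and a median of 0.93. PHGDH rose from 22.4 to 80.4 ± 41.6 CPM, the mitochondrial enzymes SHMT2 from 115.1 to 243.0 ± 53.2 CPM and PCK2 from 43.1 to 116.9 ± 38.3 CPM. The camera adjusted p was 0.00206 (adjusted p 0.747 with an estimated correlation), and 5 members rose with the GC correction, which left PCK2 at an adjusted p of 0.118. Adjusted over the list alone, 8 were higher and 1 lower with the GC correction. ATF4 itself went from a log2 change of 0.40 to 0.006 with it, TRIB3 from 0.70 to -0.05 and CEBPB from 0.67 to -0.55. Of the steroid receptors, PGR (log2 -1.03), NR3C1 (-0.63) and ESR1 (-0.55) fell, over all genes and adjusted over the list alone. The list's camera adjusted p was 0.0178, with an adjusted p of 0.747 under an estimated correlation, 0.0555 with the GC correction and 0.0779 without AROE replicate 2 under enzalutamide.

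The histone list in AROE cells held 6 genes that fell and 1 that rose, H2BC12 (log2 0.68, and -0.08 with the GC correction), with the same numbers adjusted over the list alone. Its camera adjusted p was 0.0938, and 0.0212 with the GC correction, where 7 fell and 0 rose, against adjusted p of 0.747 and 0.896 with an estimated correlation. Androgen response genes moved both ways, with 5 risers (TMPRSS2, ALDH1A3, ABCC4, SLC45A3 and NDRG1) and 4 that fell (ACSL3, ZBTB10, HERC3 and SGK1), the same numbers adjusted over the list alone, and a camera adjusted p of 0.861; the median of -0.05 and the mean of 0.12 differed in sign. With the GC correction 6 rose and 0 fell over all genes, and 8 rose and 4 fell adjusted over the list alone. Among cell cycle genes 9 rose, led by the helicase subunit MCM5 (1.28, and 0.87 with the GC correction) and thymidine kinase TK1 (1.22, and 0.31). Another 4 fell, among them the topoisomerase TOP2A (-0.53, and -0.28 with the GC correction). The GC correction gave 10 that rose and 0 that fell over all genes, and 11 and 5 adjusted over the list alone. The luminal genes had 5 risers, including the epithelial factor ELF3 (1.15), and AGR2 (-0.94) and ESR1 falling, while 2 rose and 4 fell with the GC correction. The estrogen response list had 7 risers, including TFF1 (1.10), and 2 that fell, PGR and the chemokine CXCL12, against 4 and 6 with the GC correction.

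Among the remaining AROE lists, 9 sterol and lipid synthesis genes rose, led by fatty acid synthase FASN (log2 1.82; 0.68 with the GC correction), and 3 fell, while 8 p53 targets rose and 3 fell. The GC correction left 3 sterol and lipid genes that rose and 1 that fell, and 4 p53 targets that rose and 0 that fell. Adjusted over the list alone, 4 p53 targets rose and 4 fell with it. The immediate early list, a sign of handling, had 4 risers, including JUNB (2.05; 0.95 with the GC correction), 0 that fell (3 and 1 with the GC correction), and a camera adjusted p of 0.0700. Mitochondrially encoded genes had 2 that fell, MT-ATP8 and MT-CO3, and basal or mesenchymal genes 2 risers, and 0 of either list passed with the GC correction. The 14 lists without a call had camera adjusted p from 0.0700 to 0.907. Over all comparisons, the median, mean and camera direction shared a sign for every list with a call. They differed in sign for lists without one: apocrine breast, sterol and lipid synthesis, xenobiotic metabolism, interferon and p53 in parental cells, androgen response and unfolded protein in AROE cells, cell cycle, sterol and lipid synthesis and unfolded protein for the difference of effects, and steroid receptors, cell cycle, sterol and lipid synthesis, xenobiotic metabolism, unfolded protein and histones between populations under enzalutamide. The AROE count of 4175 genes was 2321 with the GC correction and 6810 in a fit of the 3 AROE libraries alone. It was 7194 without parental replicate 1, 6806 without parental replicate 2 and 2672 without AROE replicate 2 under enzalutamide.

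**Figure D2:**
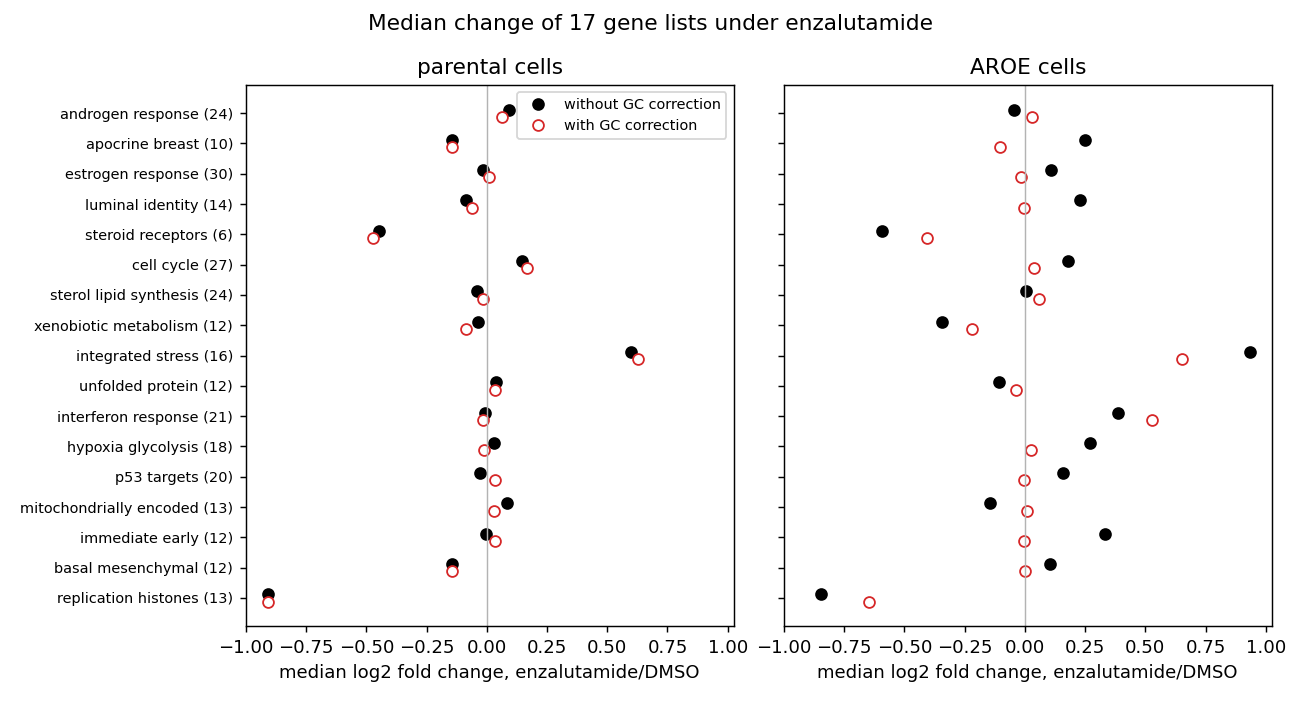
Median log2 fold change, enzalutamide over DMSO, of 17 gene lists in parental (left) and AROE (right) cells, without (filled) and with (open) the GC correction, with the number of measured genes in brackets. The histone list lies lowest in both panels (-0.91 and -0.85 without the correction), and the interferon list lies at -0.01 in parental and 0.39 in AROE cells.

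Parental and AROE cells shared many of their changed genes. Of the 62 genes that rose in parental cells, 57 also rose in AROE cells, where 7.97 would be expected of independent lists, and of the 57 that fell, 46 also fell (2.85 expected). The shared genes in the GC-corrected fits numbered 196 that rose (13.0 expected) and 258 that fell (16.0 expected). The comparisons used different libraries, DMSO included, but the tests took each gene's spread from a single fit. A gene with a small spread could thus pass in both more easily, so the expected numbers may be too low. Across 11437 genes, which are not independent replicates, the correlation of the effects (Pearson's r) was 0.16 without the GC correction, and 0.58 with it across 11434 genes.

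**Figure D3:**
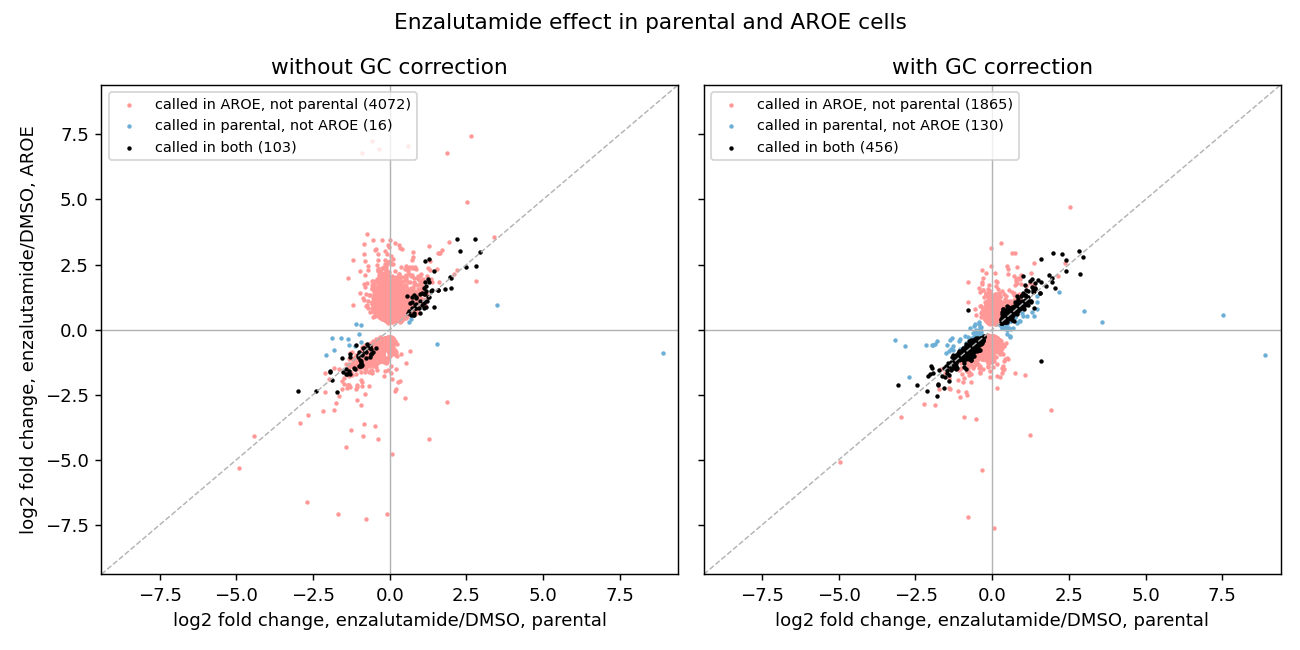
Log2 fold change, enzalutamide over DMSO, in parental (horizontal) and AROE (vertical) cells for genes that passed the test in either, without (left) and with (right) the GC correction, with 1 point per gene and the diagonal dashed. Genes that passed in both (black) numbered 103 without and 456 with the correction.

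The drug effect over both populations was estimated with the population as a term, from 4 enzalutamide and 2 DMSO libraries. STRA6 rose with a log2 change of 2.65 (SE 0.28), CP 2.44 (SE 0.18), DHRS3 1.82 (SE 0.18), TGM2, the tissue transglutaminase, 1.58 (SE 0.18) and KRT4, a keratin of stratified epithelia, 1.54 (SE 0.15). TGM2 was at 74.4 and 54.7 CPM in the parental and AROE DMSO libraries and at 176.6 ± 14.1 and 208.5 ± 34.1 CPM under enzalutamide (SD, n = 2 each). KRT4 was at 29.6 and 22.4 CPM in DMSO and at 71.8 ± 0.400 and 79.5 ± 5.96 CPM under enzalutamide. BNIPL (-1.56), MME (-1.50), CAV1 (-1.47), KCNJ8 (-1.45), ANKRD35 (-1.33), NPY1R (-1.33), TNFSF10 (-1.22) and the sialyltransferase ST8SIA4 (-1.21) fell, with every enzalutamide library below the DMSO library of its population. Their adjusted p in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment lay between 0.00928, for CP, and 0.0331, for KCNJ8 and TNFSF10. TRIM31 (1.99), NRAD1 (1.79) and KDR (1.69) completed the genes with the largest increases.

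Over both populations 76 genes rose and 101 fell. The androgen response genes TMPRSS2 (log2 0.89), ALDH1A3 (1.24) and ABCC4 (0.72) rose and 0 fell, against 8 and 3 adjusted over the list alone and 7 and 4 with the GC correction, and the list's camera adjusted p was 0.192. HK2 (0.78) rose, and AGR2 (-0.78), a disulfide isomerase of secretory cells, fell. Of 13 histone genes 4 fell (H2BC8, H2BC4, H2AC6 and H4C8; 7 adjusted over the list alone), with a camera adjusted p of 1.78e-06 (adjusted p 0.591 with an estimated correlation). The integrated stress list (median 0.70; adjusted p 9.97e-07; 12 higher adjusted over the list alone) and the steroid receptor list (median -0.47; adjusted p 0.000243; 5 lower adjusted over the list alone) had 0 members past the test over all genes. The same 0 held for the cell cycle list (adjusted p 0.0308; 10 higher adjusted over the list alone) and the interferon list (adjusted p 0.0233; 0 adjusted over the list alone). With an estimated correlation the adjusted p was 0.795 for interferon and 0.591 for each of the other 3 lists. The GC correction had 11 cell cycle, 5 integrated stress and 2 interferon genes higher and 4 steroid receptors lower over all genes. Adjusted over the list alone, it had 12 cell cycle genes higher and 5 lower. The cell cycle adjusted p was 0.203 without parental replicate 1 and 0.147 without AROE replicate 1 under enzalutamide, and the interferon adjusted p was 0.0947 without parental replicate 2 and 0.147 without AROE replicate 1. Without parental DMSO the adjusted p was 0.234 for the cell cycle and 0.0959 for histones, and without AROE DMSO 0.898 for interferon. The 12 lists without a call had camera adjusted p from 0.162 to 0.977.

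With the replicate number as a block, 27 genes changed over both populations, and 16 of the 25 named genes that had passed there no longer did. With the block and the GC correction 1627 changed, and 0 of the 25 were lost. The count of 177 over both populations was 1658 with the GC correction, 780 with DESeq2, 682 with no filter, and 0 with at least 5 CPM in 2 libraries by edgeR, where 1865 genes had an unadjusted p under 0.05. It was 4174 without parental DMSO, which leaves a comparison within AROE cells, 102 without AROE DMSO, 71 without parental replicate 1, 0 without AROE replicate 1 (2029 at an unadjusted p under 0.05) and 4 (CP, PTPRH, TGFBI and STRA6, with PTPRH named after its value was seen) without AROE replicate 2 under enzalutamide.

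**Figure D4:**
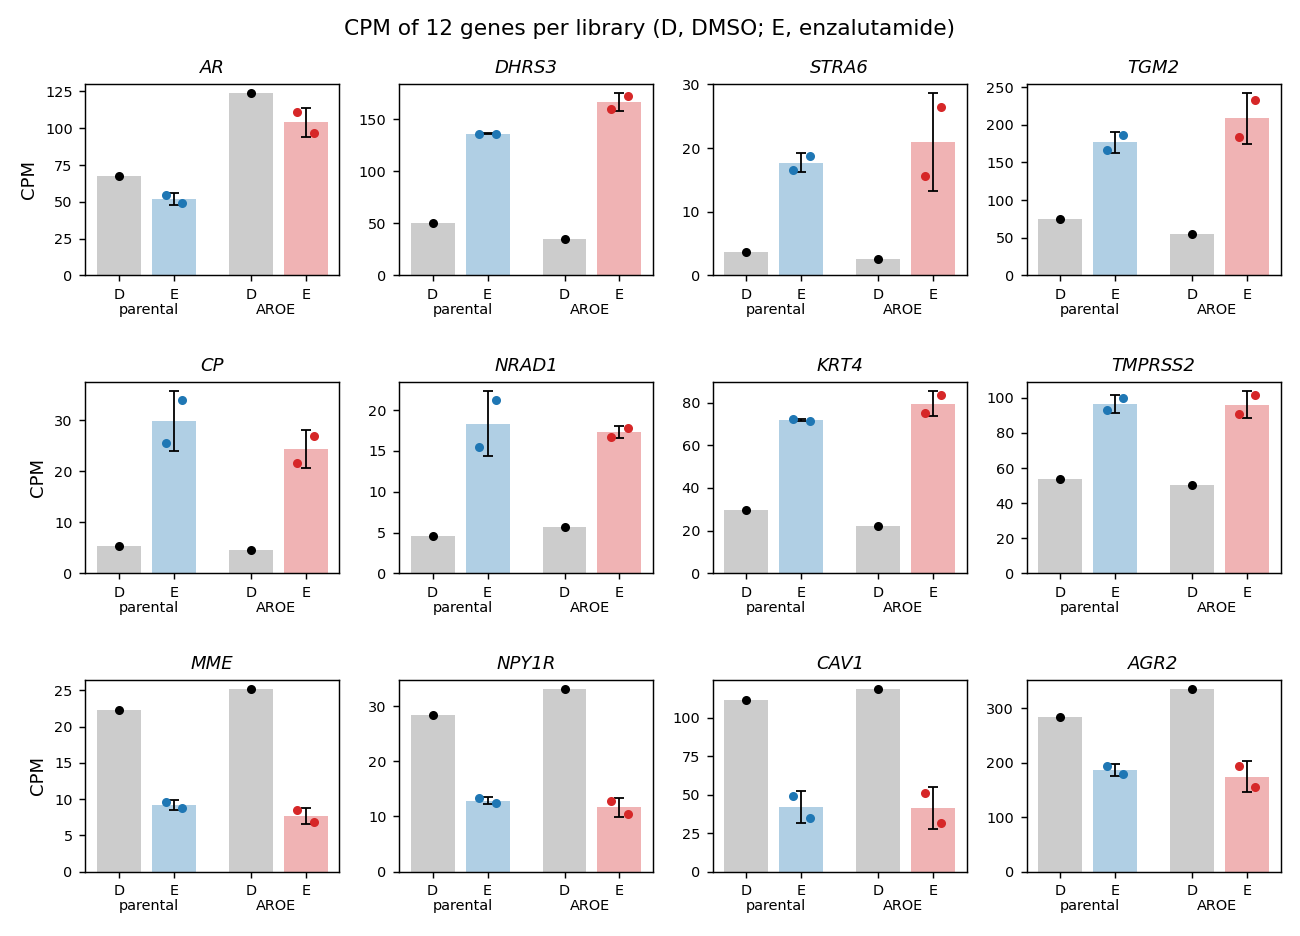
CPM of 12 genes in DMSO (D, 1 library) and under enzalutamide (E, bars at the mean of 2 libraries with SD, points at each library) in parental and AROE cells, on axes that start at 0. AR is higher in AROE than in parental cells under either treatment, and DHRS3 rises from 50.1 to 136.2 CPM in parental and from 35.3 to 166.7 CPM in AROE cells.

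Whether the drug effect differed between the populations was tested as an interaction. MIF had the largest difference, with a log2 effect 3.69 higher in AROE cells (SE 0.54): it was at 7.11 CPM in parental DMSO, 5.94 ± 3.32 in parental enzalutamide, 1.09 in AROE DMSO and 11.9 ± 1.93 in AROE enzalutamide libraries (SD, n = 2). The effect on NDUFS7, a complex I subunit, differed by 2.63, on ISG15 by 2.58, on the nucleoside diphosphate kinases NME3 and NME2 by 2.55 and 2.41, on LRFN4 by 2.54, on CLDN3 by 2.48 and on the ADP-ribosyltransferase PARP10 by 2.37. Each of these 8 had an adjusted p of 0.0103 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With the GC correction the differences were 2.37 for MIF, 1.84 for NDUFS7, 1.53 for ISG15, 1.26 for NME3, 1.62 for NME2, 1.04 for LRFN4, 0.90 for CLDN3 and 0.97 for PARP10, and LRFN4 no longer passed (adjusted p 0.0817). All 8 were below their parental DMSO level in the AROE DMSO library. NME2 has a read-through transcript with its neighbour, and MIF, NME3, LRFN4 and PARP10 overlap other genes, so their counts are less certain.

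The effect differed for 1607 genes, 1600 of them higher in AROE cells (99.6%) and 7 lower. It differed for 149 genes with the GC correction, 77.9% of them higher and 33 lower, of which 103 had passed in the same direction without the correction. The interferon list was the 1 list with a call, with 6 of 21 members higher, 7 adjusted over the list alone, a median difference of 0.57 and a camera adjusted p of 0.00345. Its adjusted p was 0.866 with an estimated correlation, 4.69e-07 with the GC correction (adjusted p 0.974 with an estimated correlation) and 0.0799 without parental replicate 1 under enzalutamide. BST2 (1.68) and OAS3 (0.98) were among its higher members, with 1.18 and 0.72 after the GC correction. The 16 other lists had adjusted p from 0.0525, for mitochondrially encoded genes, to 0.935; JUNB (2.22), FASN (1.94), MCM5 (1.04) and TFF1 (1.06) were single members with a difference that passed with and without the GC correction. The count was 5647 without parental replicate 1 under enzalutamide, and 1052 with at least 5 CPM in 2 libraries.

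AROE and parental cells were also compared under enzalutamide alone, 2 libraries against 2. The populations differed in AR level and may have differed in doxycycline, whose use per library is not stated. Differences between them can therefore not be assigned to AR level. AR, with its log2 difference of 1.00, was the 1 gene that passed of 23400, and 2719 had an unadjusted p under 0.05. The next smallest p among higher genes belonged to ISG15, at 39.9 ± 11.6 CPM in parental and 91.8 ± 10.5 CPM in AROE cells (log2 1.20, SE 0.16, adjusted p 0.0785 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), followed by PARP10 (1.05), BST2 (0.89) and the antiviral membrane protein IFITM3 (0.64). Among lower genes 0 passed, and the smallest p belonged to the mitochondrial ribosomal RNA MT-RNR2 (-0.31), TOP2A (-0.32), the kinetochore motor CENPE (-0.42) and the processed pseudogenes HMGB1P6 (-0.45) and PPIAP22 (-0.47), which share sequence with their parent genes. With the GC correction 7 genes passed: AR (1.05), ISG15 (0.80), IFI27 (0.80), IFITM1 (0.62) and IFITM3 (0.48) were higher, and NPIPB13 (-3.69) and GOLGA2P7 (-1.32), members of multicopy families with uncertain counts, were lower. IFITM1, NPIPB13 and GOLGA2P7 are named after their values were seen.

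The interferon list was higher in AROE cells under enzalutamide, with positive values for 20 of 21 members and a median of 0.26. None passed over all genes and 7 passed adjusted over the list alone. The camera adjusted p was 0.000226, against an adjusted p of 0.953 with an estimated correlation and 0.435 without parental replicate 1. The androgen response list had a median of -0.04 and 0 members past the test, with a camera adjusted p of 0.461, and the 16 lists without a call had adjusted p from 0.137 to 0.899. DESeq2 passed 474 genes (470 higher, 4 lower: CENPE, PPIAP22, GOLGA2P7 and HMGB1P6), limma-voom 2 (AR and ISG15), edgeR with no filter 1031, and edgeR 0 with at least 5 CPM in 2 libraries (1753 at an unadjusted p under 0.05). With the replicate number as a block edgeR passed 950 genes, and 463 with the GC correction added. The count was 3467 without parental replicate 1, 32 without parental replicate 2, 355 without AROE replicate 1 and 54 without AROE replicate 2.

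The AROE and parental DMSO libraries, 1 of each, compare these libraries and have no replicate check. Besides AR, the largest positive log2 ratios among genes with a mean of at least 5 CPM were below 1: C9orf40 (0.56), the lysosomal protein CLN5 (0.55), GIN1 (0.54), the mitochondrial creatine kinase CKMT1B (0.53), ZNF92 (0.52), GKAP1 (0.51) and the antisense RNA KCNQ1OT1 (0.49). The largest negative ratios belonged to NME3 (-1.58), the deubiquitinase JOSD2 (-1.52), CLDN3 (-1.51), NME2 (-1.42), SCAND1 (-1.41), the ATP synthase subunit ATP5F1D (-1.40), ISG15 (-1.38) and the chloride channel CLIC3 (-1.38). ISG15 had 4244 reads in parental and 1680 in AROE DMSO. After the GC correction these 8 negative ratios lay between -0.46 and -0.91. CKMT1B has a near-identical paralog and ZNF92 belongs to a large gene family, so their counts are uncertain.

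Of 11013 genes with a mean of at least 5 CPM in the DMSO pair, 0 were at least 1 log2 unit higher and 118 at least 1 lower in AROE cells, and with the GC correction 0 were higher and 2 lower, the metallothionein MT2A (-1.05) and the glycolytic enzyme ALDOA (-1.01), named after their values were seen. Across 11437 genes, which are not independent replicates, the AROE minus parental differences under DMSO and under enzalutamide had a Pearson's r of -0.88, and -0.56 with the GC correction across 11434 genes. A model with the spread of the enzalutamide pairs gave 1 gene, the pseudogene GUSBP13, whose counts are uncertain, and 2939 genes at an unadjusted p under 0.05; with the GC correction it gave AR, MT2A and GUSBP13, all from single libraries.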

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

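Of the tests below, those of the GC trend, transcript length, the AROE DMSO library and parental replicates 1 and 2 were chosen after the results were seen, while those of depth and a stronger response were written beforehand.

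The enzalutamide effect differed between AROE and parental cells in an interaction test for 1607 genes. The named genes singled out by this test were MIF (log2 difference 3.69), NDUFS7 (2.63), ISG15 (2.58), NME3 (2.55), LRFN4 (2.54), CLDN3 (2.48), NME2 (2.41) and PARP10 (2.37), each higher in AROE cells, and of the gene lists the interferon response list (median difference 0.57; adjusted p 0.00345 by camera, and adjusted p 0.866 with an estimated correlation).

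In AROE cells under enzalutamide, 72.0% of changed genes were higher. A deeper AROE DMSO library cannot account for this, since thinning every library to the smallest total, 82797992 reads, left 72.1% higher (2888 and 1116 genes). With each library's GC trend removed the share was 51.3%, in line with the trend as the source of the excess. The trend argues poorly for the whole response, because 1390 of the 4175 genes (33.3%) passed in the same direction after its removal. The top-decile medians also differed between the parental enzalutamide replicates 1 and 2, at 0.13 and -0.28, so the trend varied between libraries with the same label. A change in GC-rich transcripts caused by the drug in AROE cells stays open, since the design cannot separate the lone AROE DMSO library from its condition.

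Of the 1607 genes whose effect differed, 103 (6.41%) passed in the same direction with the GC correction, so the GC trend may account for most of this count. A trend on the length of the longest transcript does not account for what was left, as 147 of the 149 genes that passed after the GC correction did so with length corrected too. Other differences between the libraries were not tested, so the 149 genes cannot be taken as free of them. A biological explanation, a stronger response to the drug at the higher AR level, was set against the ratio of AROE to parental effects over 1658 genes changed over both populations with the GC correction. The median ratio was 1.15, with quartiles over single genes of 0.919 and 1.51. These genes had passed a fit whose spread includes the difference of effects between the populations, which favours genes with like effects. An effect of equal size and a somewhat stronger one cannot be told apart here, because 1 DMSO library enters every effect of a population and no value shows how far the median would move with another.

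The interferon list rose more in AROE cells, and its genes include ISG15, singled out above. The GC trend is argued against by the list's median difference, 0.58 after the correction, with a camera adjusted p of 4.69e-07. With an estimated correlation the adjusted p was 0.974 after and 0.866 before the correction. The list stood lowest of all libraries in AROE DMSO, at -0.32 from the gene means against -0.06 in parental DMSO, -0.20 and 0.09 in the parental and 0.27 and 0.22 in the AROE enzalutamide libraries, so that library supplied part of the difference. Taken as the whole cause, a low AROE DMSO library would leave little gap in the 4 enzalutamide libraries alone. There AROE lay above parental cells by a median of 0.37 (quartiles 0.22 and 0.47, positive for 20 of 21). Camera gave p 1.70e-09 there with the preset correlation and p 0.102 with an estimated correlation. These libraries also enter the difference that singled out the list, so the gap is not separate evidence. A low AROE DMSO library together with a low parental replicate 1 was not excluded. A low level in parental replicate 2 is argued against by the list standing higher there than in replicate 1, by a median of 0.30 (quartiles 0.09 and 0.70, positive for 17 of 21), though ISG15 was lower, at 31.7 against 48.1 CPM. A low level in parental replicate 1 cannot be excluded: against replicate 2 the difference was 0.20 (quartiles 0.02 and 0.51, positive for 16 of 21), and too few libraries decide it. An effect of AR level on interferon-stimulated genes, which the design names, and of doxycycline, whose use per library is not stated, stay open as untested explanations.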

How the results depend on the processing

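The GC settings and fits that combine the GC trend with length or the block were chosen after seeing the data, and the other settings were planned. Of values that answer a comparison, 65 stayed within 1.5 times the main value and 76 moved beyond it. Of the values of named genes and of lists with a call, 5440 kept their side of the threshold, 670 passed it only in the alternative, 299 no longer passed and 19 changed sign between fits of which at least 1 passed. The 5440 include 78 gene values that passed in neither fit and changed sign, 61 of them with a GC setting. Over all 17 lists, 64 of 782 values changed direction, 0 of them with a call in either fit. The cause of these differences was not tested unless given. Library totals were 82797992 to 96116658 reads. Thinning to the smallest total gave 2888 higher and 1116 lower genes in AROE cells, against 3007 and 1168, and other depths were not tried. In simulation of the parental comparison at these totals 32% of 1.5-fold changes passed, against 98% of 3-fold changes. In a fit left with a lone library in an arm, that library is assumed to vary like the others.

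Counts are given for parental, AROE, difference, AROE against parental under enzalutamide, and both populations, where they moved; the main counts were 119, 4175, 1607, 1 and 177. With no filter they were 544 (parental), 1031 (under enzalutamide) and 682 (both populations). With at least 5 CPM in 2 libraries, which tests fewer genes, they were 4 (parental), 1052 (difference), 0 (under enzalutamide) and 0 (both), with 1753 and 1865 genes at an unadjusted p under 0.05 by edgeR for the zeros. DESeq2 gave 261 (parental), 474 (under enzalutamide) and 780 (both). Under enzalutamide, median-ratio factors, library totals and limma-voom each gave 2, AR and ISG15.

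The GC correction gave 586, 2321, 149, 7 and 1658 genes, and with length added 639, 2452, 174, 4 and 1728. Fits on the groups compared alone gave 356 in parental cells, 6810 in AROE cells and 0 under enzalutamide by edgeR (2508 at an unadjusted p under 0.05). An adjusted p under 0.01 left 25, 2240, 0, 1 and 2 genes (4619 at an unadjusted p under 0.05 for the difference; 1920 by DESeq2 at 0.05), and under 0.10 gave 211, 5647, 2203, 2 and 383.

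With each library left out in turn, the lowest and highest counts were 102 and 2340 in parental cells, 2672 and 7194 in AROE cells, 1451 and 5647 for the difference, 1 and 3467 under enzalutamide, and 0 and 4174 over both populations. The extremes came without AROE DMSO and parental replicate 1, without AROE replicate 2 and parental replicate 1, without AROE replicate 2 and parental replicate 1, without either DMSO library and parental replicate 1, and without AROE replicate 1 and parental DMSO, in this order. The number of lists called lay at 3 to 5 in parental cells, 2 to 3 in AROE cells, 0 to 1 for the difference (0 without parental replicate 1), 0 to 2 under enzalutamide (0 without parental replicate 1; 2, interferon and integrated stress, without parental replicate 2 or AROE replicate 1) and 3 to 5 over both.

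The main list counts were 5, 3, 1, 1 and 5 of 17. With an estimated correlation 0 lists passed in each of the 5 comparisons, and library totals gave 2 for the difference. The DMSO pair, with 118 genes, had 246 at a mean of at least 1 CPM, 965 at a log2 ratio of 0.58, 2 with the GC correction and 1 in a test with the spread of the enzalutamide pairs.

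The replicate numbers were shared by only 2 pairs, and the labels name no shared batch or day, so the numbers were not taken as pairs. The numbers at the end of the headers follow them in both populations, with no stated meaning. The differences of replicate 1 and 2 in the populations had a correlation across genes of 0.02, and 0.31 after the GC correction. With the replicate number as a block the counts were 509, 4914, 2275, 950 and 27, and with the block and the GC correction 2008, 4432, 1127, 463 and 1627.

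The 19 sign changes in which a fit passed all went with a GC setting, and values are given for the GC correction, with length, and with the block. In AROE cells H2BC12 (main log2 0.68) was at -0.079, -0.068 and -0.081, RARA (0.84) at -0.085, -0.077 and -0.087, SDF2L1 (0.87) at -0.29, -0.28 and -0.29, SPDEF (1.06) at -0.010, -0.0030 and -0.012, and TAGLN (0.40) at -0.031, -0.020 and -0.033. For the difference, BBC3 (1.24) was at -0.41, -0.39 and -0.41. Under enzalutamide CEBPB (0.26) was at -0.29 with the block and GC correction.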

Other observations

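Of the tests below, those on the second retinoid list were written before its values were seen, and those on the header numbers after.

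Some genes known to answer to retinoic acid rose in the test over both populations. The retinoic acid hydroxylases CYP26A1 and CYP26B1 rose with log2 changes of 1.14 and 1.33 over both populations, and HOXA1, a homeobox gene that retinoic acid induces, by 1.58, all at low levels of 1.17 to 2.62 CPM in DMSO and 2.97 to 6.74 CPM under enzalutamide. These genes were noticed among the changed genes, together with DHRS3, STRA6 and TGM2. A list of 17 further genes known as retinoid responders was then fixed without their values. Of these, HOXB1, HOXB2 and HOXB3 rose, and with the GC correction 6 rose, namely these 3 (log2 1.68, 1.09 and 1.20) and TNFAIP2 (0.94), TSKU (0.67) and ICAM1 (0.96), with adjusted p from 0.000536 to 0.0152 in edgeR's quasi-likelihood test. None of the 17 fell, and 14 had positive changes; HOXA3 was at -0.14, MEIS1 at -0.39 and CYP26C1, near the floor of detection, at -1.51. HOXB2 and HOXB3 overlap an antisense gene, and neighbouring HOXB genes are not independent. The same holds for the HOXA genes of the second list and HOXA1, which had already been seen to rise.

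A hypothesis from this is that retinoic acid signalling may be higher in MCF7 cells under enzalutamide. The test was whether the second list stood above other genes: camera gave p 1.51e-06 with the GC correction and p 0.0187 with an estimated correlation (median log2 change 0.46), a single test that needed no adjustment. The result is consistent with the hypothesis. ALDH1A3, which makes retinoic acid, rose in both populations, but whether the drug acts through it, through AR or otherwise was not tested, and TNFAIP2 and ICAM1 also answer to inflammatory signals.

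The headers of the enzalutamide columns end in 10 for replicate 1 and 20 for replicate 2, while the labels give 10 µM for each. Over 1658 genes changed over both populations with the GC correction, replicate 2 lay farther from DMSO than replicate 1 in both populations for 57.2%, against a median of 28.1% and a highest value of 32.2% over 1000 random sets of genes. The random sets came from the other genes, with directions shuffled. Genes that change together under the drug are not independent. These sets therefore do not show how often pairs of libraries would differ this way. The median further shift was 0.07 log2 units in parental and 0.09 in AROE cells. The hypothesis that the numbers mark different exposures to the drug may explain this, and so could any other difference in handling that the replicate numbers share. If so, the pairs are not plain replicates and their spread, on which the p-values rest, includes a difference of exposure.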
